A study of Mus musculus with 2 samples.

How the data were processed

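Gene expression was measured in cells of the Tie2Cre lineage sorted from mouse hearts at embryonic day 12.5. Tie2Cre is a transgene that recombines loxP sites in endothelial cells, endocardial cells and their descendants, among them the mesenchyme of the endocardial cushions, and also in blood cells. Per the labels' protocols, hearts were dissociated with collagenase and dispase, dead cells were marked with DAPI, and live lineage cells without the blood markers CD41, CD45 and Ter119 were collected by flow cytometry. RNA was taken up in the lysis buffer of a small-scale kit, labelled with biotin and hybridised to Affymetrix 1-colour arrays. There was 1 array of control cells, with 1 working and 1 floxed Tbx20 allele, and 1 array of mutant cells, with 1 floxed and 1 null allele. Both genotypes carry Tie2Cre, so where it recombines, control cells keep 1 working allele and mutant cells none. The null allele is part of the animal's genotype, so cells outside the lineage would carry it too. Whether embryos were pooled is not stated in the sources used here. Xist and Y-linked genes gave signal on both arrays, as a pool of female and male embryos on each would.

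The deposited values are intensities, 1 per probe set, made with MAS5 per the submitters' processing notes. MAS5 is the Affymetrix method that combines perfect-match and mismatch probes into a linear signal and scales each array to a common trimmed mean. The deposited columns bear this scaling, since the mean without the lowest and highest 2% of probe sets was 500 on each array. The software version, the background settings and the genome build are not given in the sources used here. A single factor per array leaves differences that vary with brightness in place, and the mismatch subtraction makes ratios of dim probe sets noisy.

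Of 45101 probe sets, 64 were array controls. Gene names came from the platform annotation: 34945 of the other 45037 probe sets named 1 gene, 932 named several and 9160 were not listed. Gene identifiers matched the reference gene table for 34754 probe sets, and 0 symbols had to be updated. Probe sets that named several genes or none were left out of gene results. Signals were used as deposited and put on the log2 scale. Values under each array's median over its non-control probe sets, 91.3 in the control and 82.4 in the mutant, were set to that floor. A gene took the value of its single-gene probe set with the highest mean log2 signal. It counted as measured where that probe set lay above the floor on both arrays. Genes above the floor on 1 array have a lower bound only, taken against the floor of the other array. The floors differ by -0.15 on the log2 scale, and this difference is part of those bounds.

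With 1 array per genotype there is no replicate check, and no p-value, standard error or test between genotypes was computed. Genes were counted by a size rule of 2-fold. For each of 32 gene lists, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart under percentile 2.5 or over percentile 97.5, as a description of these 2 arrays. Lists with fewer than 5 members above the floor on at least 1 array, those of liver and sex-linked genes, got no value. The internal measure of error was the agreement between probe sets of 1 gene, which share the same RNA and so cover probe error and not animals. The number of arrays limits the precision.

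The lists, the counting rules and the rule for named genes were fixed before the data were examined. That rule takes Tbx20, then the 12 genes with the highest and the 12 with the lowest ratio among genes whose measured probe sets all moved the same way. A gene with 1 measured probe set met this condition by default, as most genes so named did. The rule adds the 4 brightest genes in each direction among those with every probe set under the floor on the other array. From each list it takes up to 4 members with the largest absolute ratio, or the brightest members for lists of other cell types. Of the members so picked, the text prints some. Genes named outside the rule are said to be so where they appear. In addition, 3 lists were written later for the closing tests.

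Alternatives were scaling to the median of measured probe sets, quantile normalization, and a loess fit of the ratio on brightness with a span of 0.3. Others were floors at the 25th and 75th percentiles, a pseudocount of each array's median with no floor, the median over a gene's probe sets, unsuffixed probe sets only, folds of 1.5 and 3, and list means. The use of only those members that no other list holds was added after seeing the data. The steps were tested on simulated data with the observed probe noise, with 200 genes changed by known amounts. In the simulation 10892 genes were above the floor on both arrays, 10706 unchanged and 186 changed. Of 50 genes with a true log2 ratio of 2, 50 were recovered at 2-fold. Of 50 at -2, 46 were recovered, but only 37 of these were above the floor on both arrays and the rest were lower bounds. At 1 and -1, 23 and 24 of 50 were recovered. With 1 noise level for all genes, 35 of the 10706 unchanged genes passed 2-fold. With the noise of each brightness class, 61 of 10811 did, 31 of them under a signal of 200. With 1 noise level, 14 of 200 unchanged lists of 25 genes stood apart. Of 20 lists shifted by 0.3, 20 stood apart as higher. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.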

Results

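Sorted Tie2Cre lineage cells of control and Tbx20 mutant hearts at embryonic day 12.5 were compared on 1 expression array each. Tbx20 is a T-box transcription factor of the developing heart. With 1 array per genotype, an effect of Tbx20 cannot be told apart from other differences between the preparations. Of 18193 genes on the array, 10665 were above the floor on both arrays and 888 on 1 array only. The log2 signals of the 21148 probe sets above the floor on both arrays correlated at r = 0.974 across probe sets, which are not independent replicates. The median log2 ratio of mutant over control was -0.01 (SD 0.38 over genes). No value below has a replicate, so differences are between these 2 arrays.

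Tbx20 itself was strongly detected on both arrays. Its 3 probe sets read 7638, 6128 and 7050 in the control and 6416, 5262 and 4245 in the mutant. The mutant signals were 84.0%, 85.9% and 60.2% of control, a mean log2 ratio of -0.40 (SD 0.29 over 3 probe sets). The brightest probe set lay at percentile 16.4 of the ratios of the 500 genes closest to it in brightness. The labels do not say which exons the floxed allele removes, so these probe sets may check nothing about the deletion.

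Genes at least 2-fold lower in the mutant outnumbered those at least 2-fold higher, 156 against 69 of the 10665 measured genes. The lower genes made up 69.3% of these calls, against 61.3% after quantile normalization, 60.7% after loess and 80.8% with a pseudocount. Another 37 genes were above the floor in the control array only and 14 in the mutant array only, each by at least 2-fold. With the floor at the 25th percentile, 537 genes were lower and 233 higher, and at the 75th percentile 34 and 12. Dim genes passed most often: 5.93% of the 1349 genes under a signal of 200 passed 2-fold, 2.25% of the 4969 genes from 200 to 1000, and 0.759% of the 4347 brighter genes. The SD between probe sets of 1 gene was 0.49, 0.36 and 0.24 in these classes. From dim to bright, 61, 68 and 27 genes were lower and 19, 44 and 6 higher. The median log2 ratios of the classes were -0.11, -0.01 and 0.01. In the simulation with the noise of each class, 61 of 10811 unchanged genes passed 2-fold.

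**Figure D1:**
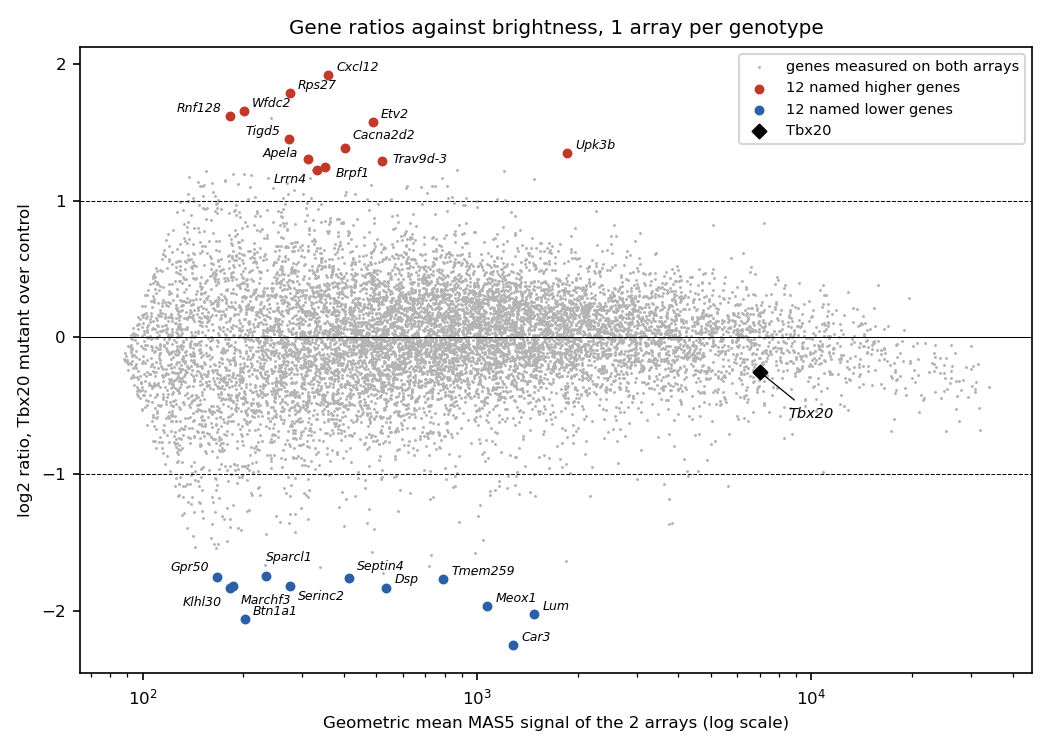
Each grey point is a gene measured on both arrays, with the geometric mean of its MAS5 signals on a log axis and its log2 ratio of mutant over control; dashed lines mark 2-fold. Car3, Lum and Meox1 lie lowest among the brighter genes and Upk3b highest, while Tbx20 sits at -0.25 at the bright end.

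Of the 12 genes lowest in the mutant, Car3, a carbonic anhydrase, read 2803 in the control and 590 in the mutant, 4.75-fold lower, and both of its measured probe sets were lower. Lum, which encodes the collagen-binding proteoglycan lumican, read 2989 and 736, a log2 ratio of -2.02. Meox1, a homeobox factor of mesoderm, read 2122 and 545 (-1.96). Dsp, the desmosome protein desmoplakin, was at -1.83, with its other measured probe set at -0.99. Septin4 was at -1.76 and Sparcl1, a matricellular protein, at -1.74. The rest of the 12 lowest were Btn1a1 at -2.06, Klhl30 at -1.83, Serinc2 and Marchf3 at -1.82, Tmem259 at -1.77 and Gpr50 at -1.75. Of these, Btn1a1 read 99.0 in the mutant, Klhl30 97.0, Marchf3 99.2 and Gpr50 91.0, close to the floor. Among the 12, only Car3, Dsp and Septin4 had more than 1 measured probe set.

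Of the 12 genes highest in the mutant, Cxcl12, a chemokine, read 184 in the control and 696 in the mutant, 3.77-fold higher, while its other measured probe set was at 0.75. Etv2, an ETS factor of early endothelial and blood development, read 283 and 841 (1.57), and Apela, a ligand of the apelin receptor, 199 and 493 (1.31). Upk3b and Lrrn4, both markers of mesothelium, stood at 1.35 and 1.22, with Upk3b read at 1163 and 2961. Wfdc2 was at 1.65, Rnf128 at 1.62, Tigd5 at 1.45, Cacna2d2 at 1.39, Trav9d-3 at 1.29 and Brpf1 at 1.25. In the control, Wfdc2 read 113 and Rnf128 104, close to the floor of 91.3. Among the 12, only Cxcl12, Upk3b, Cacna2d2 and Trav9d-3 had more than 1 measured probe set. Rps27, a ribosomal protein, was at 1.79 from a control signal of 148, although 28 of the 30 members of the ribosomal list were lower. Above the floor in the mutant only were Hoxb3, at least 3.79-fold higher, Gm15886, at least 3.10-fold, Ntm, at least 3.08-fold, and Thsd7b, at least 2.48-fold. In the control only were Rpl39, at least 4.06-fold lower in the mutant, Hspa1a, at least 3.02-fold, Cx3cr1, at least 2.74-fold, and P2ry6, at least 2.66-fold. Hspa1a has a near-identical copy, Hspa1b, so its probe sets are uncertain.

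Genes of cushion and valve extracellular matrix were lower as a group. Of 52 measured members, 41 were lower and 11 higher, with a median log2 ratio of -0.27 at percentile 0.00 of random lists. Besides Lum, Col2a1 was at -1.35, Matn4 at -1.28 and Thbs1 at -1.16, with its second probe set at -1.12. Matn4 read 91.4 in the mutant, close to the floor. The 8 members with a control signal over 10000, a limit set after their values were seen, were Postn at -0.73, Vcan at -0.50, Col4a1 at -0.21, Fn1 at -0.20, Sparc and Col18a1 at -0.19, Col3a1 at -0.07 and Col1a2 at 0.06. Dcn, also named after its value was seen, was the highest member at 0.59. The list of cushion mesenchyme and EMT regulators had 18 of 27 members lower and a median of -0.16 (percentile 1.24). Meox1 was lowest there, followed by the tendon and valve factor Scx at -1.35, Msx1 at -1.08 and Snai2, an EMT repressor of cadherins, at -0.89. The median was -0.26 with the higher floor and -0.37 over members that no other list holds. Markers of epicardium moved the other way in the same arrays, with a median of 0.62, and erythroid genes had a median of -0.58.

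The lists of the sorted lineage's own markers had medians near 0, with single members that differed. The pan-endothelial list had a median of -0.04 (percentile 33.8) over 32 members, with 0 at 2-fold in either direction and extremes at Robo4 (-0.72), Cldn5 (-0.70), Clec14a (-0.53) and Rasip1 (0.41). The endocardial list had a median of 0.07 (percentile 82.8), with 12 of 21 members higher, 1 of them at 2-fold and 1 lower member at 2-fold. Its widest members went both ways, with Bmp6 read at 1285 and 403 (-1.67), Cytl1 at -0.85, Irx3 at 1.16 and Dll4 at 0.62. With the median over a gene's probe sets the endocardial median was 0.17 and stood apart. The coronary and vascular list had a median of -0.08 (percentile 20.6). Fabp4 was at -1.14, Aplnr at -0.88 with its other probe set at -0.23, Car4 at 0.97 and Pdpn at 1.22. Pdpn read 101 in the control, close to the floor. Of the 21 members of this list, 1 was at least 2-fold higher and 1 lower. Its sign turned with unsuffixed probe sets (0.15), the median over probe sets (0.05) and members of 1 list only (0.07).

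**Figure D2:**
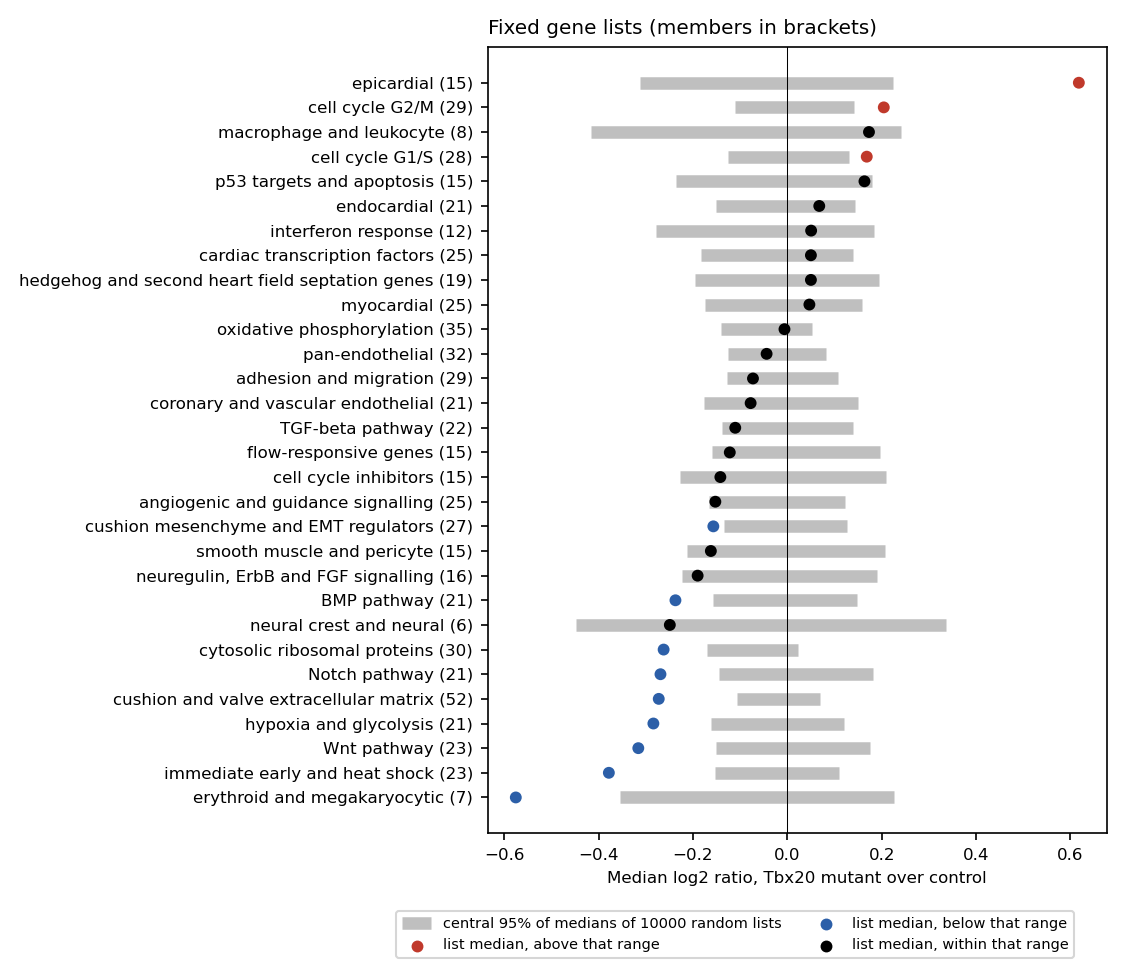
Points are the median log2 ratios of mutant over control of the 30 gene lists with a value, and grey bars span the central 95% of medians of 10000 random lists matched on expression. The epicardial list lies farthest above its bar at 0.62 and the 9 lists in blue lie below theirs.

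The BMP, Notch and Wnt lists were lower in the mutant array. The BMP pathway had 15 of 21 members lower and a median of -0.24 (percentile 0.21), with the ligands Bmp6 at -1.67 and Bmp2 at -1.44, the BMP-binding protein Bmper at -1.26 and the inhibitory Smad7 at -0.95. Its second Smad7 probe set was at -0.31, and the list no longer stood apart with the lower floor or a pseudocount (-0.10 in both). The Notch pathway had 14 of 21 members lower and a median of -0.27 (percentile 0.02), with the target genes Heyl at -0.93 and Hes1 at -0.63 and the ligands Jag2 at -0.88 and Dll4 at 0.62. With the median over a gene's probe sets the Notch median was -0.10 and did not stand apart. The Wnt pathway had 19 of 23 members lower and a median of -0.32 (percentile 0.03), with the modulators Sfrp2 at -0.87 and Dkk3 at -0.76, the target Axin2 at -0.71 and Lef1 at -0.70. The second Axin2 probe set was at -0.27. These pathway lists mix ligands, receptors, modulators or effectors, and targets, so their medians give no direction of signalling. TGF-beta genes did not stand apart, at a median of -0.11 (percentile 6.06), but did as lower with the higher floor or unsuffixed probe sets (-0.15 in both) and as a mean (-0.22). They included Thbs2 at -1.14 and Tgfb2 at -0.95, while Tgfb1 was at 0.63. The highest of the measured Tgfb2 probe sets was at -0.31. Erythroid genes, at a median of -0.58, were lower in the same array.

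Proliferation genes were higher as a group. The G1/S list had 21 of 28 members higher and a median of 0.17 (percentile 99.4), with Mcm10 at 0.84, the cyclin gene Ccne1 at 0.73 and Chaf1b at 0.66. The G2/M list had 21 of 29 members higher and a median of 0.20 (percentile 99.9). There the mitotic kinase gene Plk1 read 572 and 1337 (1.22), Cenpe was at 1.02 and Aurkb at 0.49, while Anln was at -0.60. Probe sets disagreed for some of these, with the lowest at 0.03 for Mcm10, Cenpe and Aurkb alike. Cell cycle inhibitors had 13 of 15 members lower, with Gadd45b at -1.57 and Cdkn1a at -0.68, and a median of -0.14 (percentile 10.4). The highest of the measured Gadd45b probe sets was at -0.79. They stood apart as lower with the median over probe sets (-0.25) and as a mean (-0.30). Epicardial markers were higher in the same array, at a median of 0.62.

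Lists of other cell types, among them blood cells that the gate removes by CD41, CD45 and Ter119, did not move together. Of 15 epicardial members, 14 were higher, and the median of 0.62 lay above all the random medians. Of the 18 genes listed, Tbx18 and Sema3d, named here outside the rule, are also held by other lists. Tcf21 read 2432 and 3367 (0.47), Gpm6a was at 0.87 and Krt18 at 0.27. A second Gpm6a probe set was at -0.12, and the list median with a pseudocount was 0.39. Erythroid and megakaryocytic genes, from cells the gate removes by Ter119 and CD41, had a median of -0.58 (percentile 0.06) over 7 members, among them Hbb-y, read at 9843 and 6606, and Hba-x at -0.97. Some globin genes have near-identical copies, and whether the Hbb-y and Hba-x probe sets also read other globins was not tested. The list no longer stood apart with the lower floor (-0.38) or a pseudocount (-0.23). Myocardial genes had a median of 0.05 (percentile 74.4), with 15 of 25 higher. Among its members, Myl7 read 3811 in the control and 6753 in the mutant (0.83), and Tnni1 7257 and 5654 (-0.36). Some myocardial transcripts thus gave strong signal on both arrays, and which cells they came from was not tested. Macrophage and leukocyte genes had a median of 0.17 (percentile 93.9) over 8 members, of which 3 were above the floor on both arrays. Smooth muscle and pericyte genes had a median of -0.16 (percentile 6.72), which stood apart with unsuffixed probe sets (-0.37), and neural crest and neural genes -0.25 (percentile 13.4) over 6 members, with Ednrb at 0.84.

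**Figure D3:**
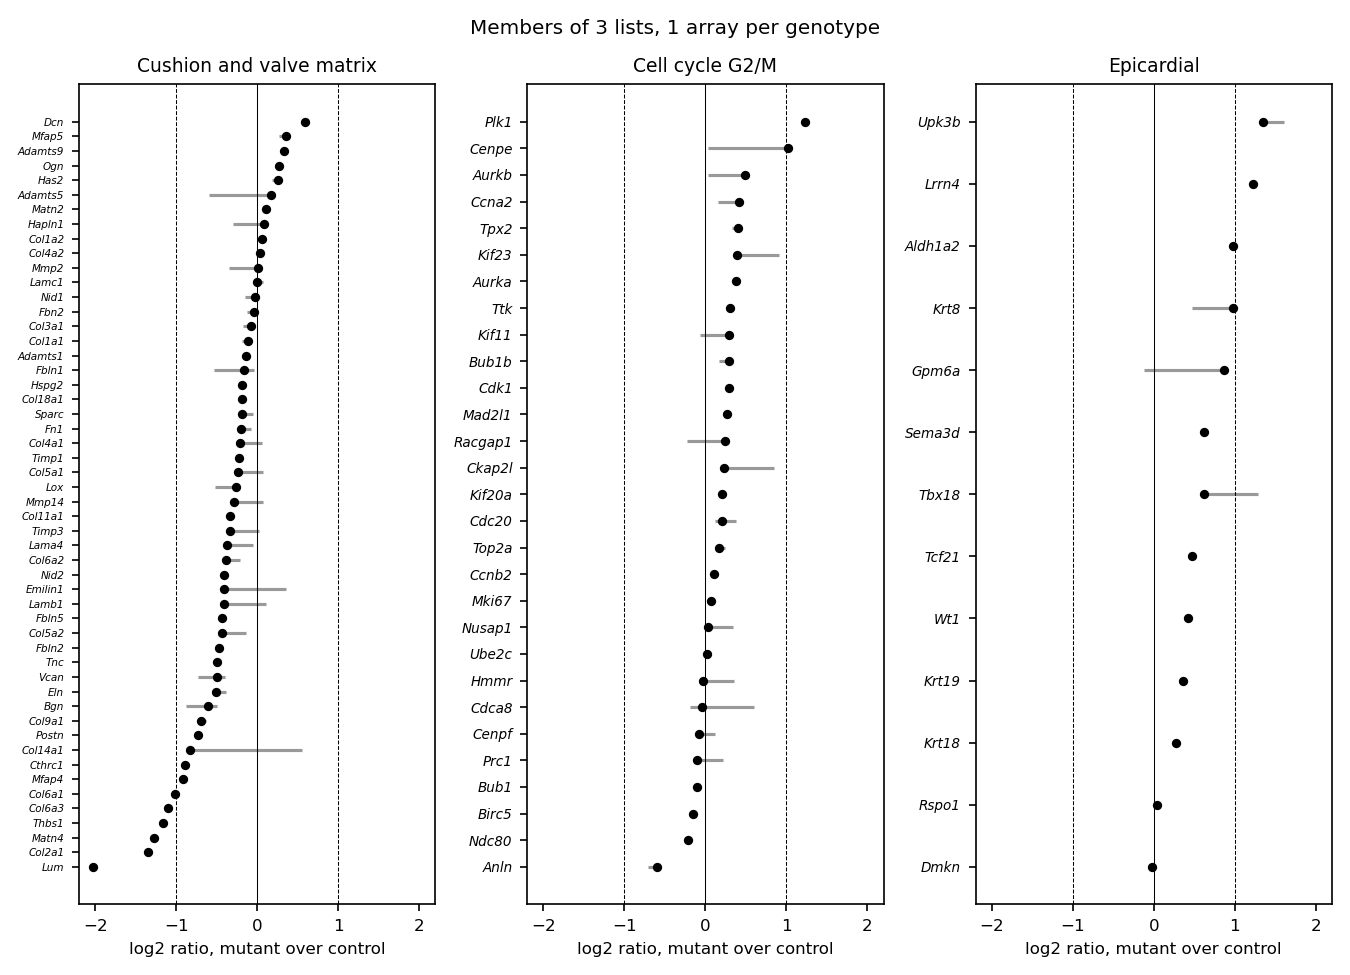
Points are the log2 ratios of mutant over control of the measured members of 3 lists, grey lines span a gene's measured probe sets, and dashed lines mark 2-fold. Lum is the lowest matrix gene at -2.02, Plk1 the highest G2/M gene at 1.22 and Upk3b the highest epicardial gene at 1.35.

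The fixed lists of immediate early and of hypoxia genes were lower in the mutant array. The immediate early and heat shock list had 19 of 23 members lower and a median of -0.38 (percentile 0.00), with Egr3 at -1.38, Ier3, read at 6017 and 2339, at -1.36 and Egr2 at -0.85. Hypoxia and glycolysis genes had a median of -0.28 (percentile 0.01), with 15 of 21 lower, including Ankrd37 at -1.02, Egln3 at -0.99, Ndrg1 at -0.97 and Adm at -0.97. The measured probe sets of Ndrg1 reached up to -0.32 and those of Adm up to -0.46, while those of Egln3 reached down to -1.70. A separate list of 19 hypoxia targets, written later, had a median of -0.07 (percentile 28.8) and did not stand apart. Ribosomal protein genes had a median of -0.26 (percentile 0.01), but -0.08 after loess and -0.01 after quantile normalization, where they did not stand apart. The 3' over 5' signal of Gapdh, a sign of RNA quality, and the spike controls were lower in the same array. In all, 12 of 30 lists stood apart, 9 lower and 3 higher. The nominal rate of chance calls is 1.5 of 30, 14 of 200 simulated unchanged lists stood apart in 1 run, and some lists share members. Both rates take genes as independent, whereas the genes of a real list may shift together between preparations. Neither is therefore a usable chance rate for these lists.

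Array controls also differed. The 18 spike probe sets were all lower in the mutant, by a mean log2 ratio of -0.45, and 18S was at -0.45. The cre spike is a hybridisation control, at -0.42, and does not report the transgene. The ratio of 3' over 5' signal for Gapdh was 2.27 in the control and 1.64 in the mutant, and for Actb 0.989 and 0.998. Agreement between probe sets was low: over 5174 genes with several measured probe sets, their log2 ratios correlated at r = 0.250 across genes and had the same sign in 56.8%. Of 88 genes at least 2-fold in the brightest probe set, 76 had the next one in the same direction and 17 had it at 2-fold too.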

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

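The loess tests, the test of overall purity and the subset of 8 mesothelial genes were chosen after the results they bear on had been seen. Of 1875 measured probe sets that named several genes or none, 16 were at least 2-fold higher in the mutant and 35 lower. They stand here because no comparison above uses them.

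Matrix genes were lower in the mutant array. A trend with brightness does not account for it, since the median of the matrix list was -0.29 after loess. Fewer mesenchymal cells among the sorted cells could contribute: a separate list of 23 collagen-processing and mesenchymal genes, written before its values were seen, had a median of -0.16 below the random range, which began at -0.15, with a median signal of 3479 in the control and 2937 in the mutant. Lower expression per cell would give the same result, and an effect of genotype was not tested, so both stay open.

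Epicardial markers were higher. Lower purity overall would raise other cell types alike, but the epicardial median exceeded the highest of the myocardial, smooth muscle and erythroid medians by 0.57. More epicardial cells should also raise other mesothelial genes that the lineage itself expresses little, but a separate list of 17, written before its values were seen, had a median of -0.060 (percentile 39.2), lower by 0.677 than the epicardial median, with an SD of 0.44 over members. Its 6 members with a control signal over 1000 could hide a small share, and the 8 others measured on both arrays had a median of -0.04 (SD 0.38), lower by 0.656. The myocardial median of 0.05 argues against lower purity for all cell types alike. Erythroid genes say little here, since the gate removes those cells. The separate mesothelial list met the bound set beforehand against more epicardial cells. It cannot decide this, since how strongly epicardial cells express the 8 genes was not measured here. The fixed list itself, with 14 of 15 members higher, is what more epicardial cells would give. It is the pattern in question, though, and no separate test. A change of expression within the lineage also stays open, untested.

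Immediate early and hypoxia genes were lower. After loess the higher of both medians was -0.23, which argues against a trend with brightness. Oxygen supply or handling time could differ between the preparations. The immediate early and heat shock list was fixed beforehand as the marker of cell handling during dissociation and sorting. Its lower median is what a difference in handling would give, but it is the pattern in question and no separate test. Hypoxia targets cannot speak to handling time. For oxygen supply, a separate list of 19 hypoxia targets had a median of -0.067 (percentile 28.8), and so neither bore this out nor met the bound set against it. Of its members, 2 had been seen before; without them the median was -0.07 (percentile 30.0). With 1 preparation per genotype, handling and genotype cannot be told apart.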

How the results depend on the processing

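All alternatives but 1 were planned; the use of members of 1 list only was added after seeing the data. Scaling to the median moves all genes alike and so could not change a list call, nor could members of 1 list where a list shares none. Of the other alternatives, the matrix, G1/S, G2/M, epicardial, immediate early and hypoxia lists stood apart under 8 of 8, and the EMT and Wnt lists under 9 of 9. The higher floor left too few epicardial, erythroid, macrophage and neural genes for a value, and unsuffixed probe sets too few erythroid genes. The median turned sign under at least 1 alternative for 7 lists, 0 of which stood apart in the main setting: coronary, cardiac factor, hedgehog, interferon, macrophage, myocardial and oxidative phosphorylation. The cause of the shifts below was not tested, except that counts follow from how many dim genes a floor admits and from the fold asked for. The genes at least 2-fold higher in the mutant and the genes at least 2-fold lower in the mutant numbered 233 and 537 with the 25th percentile floor, 12 and 34 with the 75th, 466 and 705 with a fold of 1.5 in place of 2, and 5 and 19 with a fold of 3. Higher genes numbered 25 with a pseudocount and 44 with the median of probe sets. The agreement between probe sets of 1 gene was r = 0.203 with the lower floor, 0.215 with a pseudocount and 0.198 with unsuffixed probe sets. The BMP median was -0.16 after loess and -0.10 with the lower floor or a pseudocount. The erythroid median was -0.38, -0.23 and, with members of 1 list, -0.97. The macrophage median was 0.37 with the lower floor, where it stood apart, -0.011 with a pseudocount and -0.037 as a mean. The EMT median was -0.26 with the higher floor, -0.28 as a mean and -0.37 with members of 1 list. With the median of probe sets the matrix median was -0.20, the endocardial 0.17 and the Notch -0.10. As means, the matrix list was at -0.35 and Notch at -0.18. With unsuffixed probe sets the pan-endothelial median was -0.11 and the G2/M median 0.29. The angiogenic list, at -0.15, stood apart under 7 of 9 alternatives that could change it and not in the main setting. No paired analysis was possible because each genotype has 1 array, and for the same reason no array could be left out. Signal near the floor limits the dim genes.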

Other observations

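The reading of the neighbour test below was changed after its result was seen. Several lists not described above stayed within their random ranges in the main setting. Angiogenic and guidance genes had a median of -0.15 (percentile 3.80), with 16 of 25 members lower, among them Vegfc at -0.95, Vegfa at -0.89 and Angpt1 at -0.73. They stood apart as lower under 7 of 9 alternatives that could change the call. Neuregulin, ErbB and FGF genes had a median of -0.19 (percentile 5.13), with Hbegf at -0.77 and the feedback inhibitor Spry1 at -0.74. The second Hbegf probe set was at -0.36. This list stood apart as lower with the higher floor (-0.21) and with the median over probe sets (-0.26). Flow-responsive genes had a median of -0.12 (percentile 6.04), with Gja5 at -0.87 and Klf2 at -0.46, while Gja4 was at 0.58. They stood apart with the median over probe sets (-0.21). Adhesion and migration genes had a median of -0.07 (percentile 14.3), with Itgb3 at -1.51 and Alcam at -1.17 but Arhgap29 at 0.48 and Itga4 at 0.47. Itgb3 read 99.6 in the mutant, close to the floor. The measured probe sets of Alcam reached up to -0.45 and those of Itga4 down to 0.0012.

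Cardiac transcription factors other than Tbx20 had a median of 0.05 (percentile 81.3), with Irx3 at 1.16 and Srf at -0.72. Its sign turned with members of 1 list only (-0.09), the median over probe sets (-0.03) and a pseudocount (-0.0084). Hedgehog and septation genes had a median of 0.05 (percentile 69.7), with Gli3 at -0.70 and Boc at 0.59. The highest of the measured Gli3 probe sets was at -0.27. Damage and apoptosis genes had a median of 0.16 (percentile 96.4) and stood apart with unsuffixed probe sets (0.23). Interferon genes had a median of 0.05 (percentile 77.6) with Ifitm3 at -0.78 and Stat2 at 0.67, whose other probe set was at -0.69. Oxidative phosphorylation genes had a median of -0.01 (percentile 75.4), whose sign turned after quantile normalization and loess and with unsuffixed probe sets. Of the lists too small for a value, liver genes included Apob at -1.35, with its second probe set at 0.26. Sex-linked genes showed Xist at 2040 and 1401, Eif2s3y at 1166 and 1323 and Kdm5d at 471 and 517 in control and mutant.

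The hypothesis that genes beside Tbx20 differ between the arrays was tested on the 10 nearest genes above the floor on each side, in the order of the reference gene table. Their median was -0.082 (percentile 23.0 of random lists), with 7 above 0 and 13 below. This met the bound set beforehand against the hypothesis, but a median near 0 over genes that go both ways says little of single neighbours, so it is left undecided. Bmper, the second gene on 1 side, was at -1.26, and Ntm, the tenth on the other, was above the floor in the mutant only.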
